A study of Arabidopsis thaliana with 12 samples.

How the data were processed

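Total RNA was extracted from buds or open flowers of primary inflorescences (10 to 50 mg per sample) and sequenced as 150-nt paired-end reads on an Illumina NovaSeq, per the labels' protocols. Plants grew under 16 h of light and 8 h of dark at 21 and 19 °C and were sampled 5 h after dawn, per the labels. The 12 libraries fell into 6 groups of 2 by genotype (ask1, ASK1 WT and Col-0) and tissue (buds and open flowers). All genotypes carried the strain label Col-0. The labels gave no pairing or batch, and replicate numbers follow only the order of deposition.

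The deposited values were read counts per gene, 1 file per library, covering 33602 genes of the TAIR10 annotation and 5 summary lines for reads outside genes. Trimmomatic, TopHat2 and HTSeq were named for trimming, alignment and counting, per the submitters' processing notes. Their versions, settings and the counting strand were not given in the sources used here. The values were whole numbers with unequal library totals and were treated as raw counts. The summary lines stayed out of library sizes and tests. They held 7.60% to 9.70% of each library, of which reads with no feature were 2.94% to 4.09%, ambiguous reads 1.06% to 1.14% and reads without a unique alignment 3.08% to 4.95%. Gene names, positions, exon lengths and products came from the TAIR10.1 annotation, in which 32835 of the 33602 gene identifiers were found.

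Depth ranged from 13780265 to 23426466 counts in genes per library. A count of 0 allowed an upper limit of 3 counts, which was 0.128 to 0.218 CPM depending on the library. The 10 most abundant genes held 2.95% to 4.40% of the counts, and TMM factors ranged from 0.936 to 1.07.

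Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9. Genes were kept with edgeR's expression filter by group (minimum count 10 and minimum total 15), which left 21890. Counts were scaled by TMM and fitted in edgeR with 1 mean per group over all 12 libraries, robust dispersion and robust quasi-likelihood estimates, and 6 residual degrees of freedom. Each contrast was tested by the quasi-likelihood F-test with Benjamini-Hochberg adjustment over all tested genes at 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Contrasts compared ask1 with ASK1 WT, ask1 with Col-0 and ASK1 WT with Col-0 in each tissue, open flowers with buds in each genotype, and the ask1 effect against ASK1 WT between the tissues. Tests, gene lists, named-gene rule and alternatives were chosen before the data were examined, except where stated.

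The 21 gene lists were tested with limma camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. The adjusted p with the correlation estimated from the data was computed beside it. Lists covered the ASK family, SCF partners with studied F-box genes, the 26S proteasome, meiosis, tapetum and pollen wall, mature pollen and pollen tube, jasmonate, Aux/IAA, SAUR and GH3, gibberellin, ethylene, salicylate and defence, floral organ identity, cell cycle, photosynthesis, circadian clock, seed and embryo, flavonoids, heat shock and handling, senescence, and 629 genes annotated as F-box. Lists of iron-deficiency, sulfur-deficiency and cold-regulated genes were added after seeing single members in the results.

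Genes were named by rule. ASK1, ASK2, CUL1, TIR1 and COI1 were always named. In each tissue, the 10 highest rises and 10 deepest falls were named among genes that passed in the same direction against both controls, had both ask1 libraries beyond all 4 control libraries, a mean of at least 1 CPM and a symbol in the annotation, ranked by the smaller of both changes. The 5 largest in each direction were named for ASK1 WT against Col-0, for the tissue difference of the ask1 effect and for the Col-0 tissue comparison, and up to 4 members per list and tissue. Not every gene named by the rule is printed, and members of the added lists, TOC1 and the other shared clock genes fall outside it and were chosen after their values were seen. Among changed genes with no symbol, 545 rose and 1420 fell in buds and 1287 rose and 1348 fell in open flowers under the same conditions.

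Where a group held 0 counts of a gene, the fold change was given as a lower bound against 3 counts over the group, and where it held 1 to 3 counts, as a ratio of counts with its 95% interval. Genes shared by both controls were compared with 20 simulated data sets without an ask1 effect. Overlaps between tissues and the share of changed genes within 1 Mb of ASK1 were tested with Fisher's exact test. Exon lengths were known for 21826 tested genes.

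The fit was tested on simulated counts for 21648 genes with known changes. Means, and a spread per gene common to all groups, came from a fit to the deposited counts. Of 2-fold changes set in buds, 44.9% of falls and 64% of rises were recovered, and in open flowers 53.1% and 60%. Of 4-fold changes, 77.1% and 86% were recovered in buds and 81.3% and 86% in open flowers. Of 21451 unchanged genes, 7 passed in each tissue. A jasmonate list raised among 21667 simulated genes (buds, ask1 against ASK1 WT) gave a camera adjusted p = 2.77e-64, and 0 of the 20 other lists passed. Correlation between members was not simulated, so list p-values were not tested for it.

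Alternatives were DESeq2's median-of-ratios (RLE) factors in place of TMM, no low-count filter, DESeq2 in place of edgeR, a fit of only the libraries compared, an added 2-fold minimum, windows of 0.5 and 2 Mb around ASK1, leaving out genes within 1 Mb of ASK1, and leaving out each library of a comparison in turn on the same 21890 genes. In the last, the remaining library of the group was assumed to vary like the other groups. Removing the trend of each library with exon length, and leaving out ask1 bud replicate 2 and ask1 flower replicate 1 together, were chosen after seeing the data.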

Results

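RNA-seq was carried out on floral buds and on open flowers of Arabidopsis thaliana plants carrying a Ds insertion in ASK1, of plants with the wild-type ASK1 allele (ASK1 WT) and of Col-0. ASK1 encodes a SKP1-like subunit of SCF ubiquitin ligases, which link F-box proteins to the cullin CUL1. The 12 libraries formed 6 groups of 2, one group per genotype and tissue. Counts in genes totalled 17246453 and 13780265 in the ask1 bud libraries, 15146001 and 18809497 in ASK1 WT buds and 17163208 and 17292209 in Col-0 buds. They totalled 16242961 and 16534841 in the ask1 open-flower libraries, 23426466 and 18007376 in ASK1 WT open flowers and 17625284 and 17261607 in Col-0 open flowers. Between 22825 and 24008 genes were detected per library. The first principal component carried 65.5% of the variance and separated open flowers from buds, and the next one carried 21.1% and separated ask1 from both controls. Across genes, ask1 buds correlated with ASK1 WT buds at r = 0.905 to 0.928, whereas ASK1 WT and Col-0 buds correlated at 0.986 to 0.989. In open flowers the same values were 0.931 to 0.943 and 0.990 to 0.992. The labels did not say that replicates came from separate plants, so every p-value measured only the spread between these samples. Changes are given as log2 fold change ± SE from edgeR with n = 2 libraries per group, and a gene is said to rise, fall or change where its edgeR quasi-likelihood p, adjusted by Benjamini-Hochberg, was under 0.05.

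The target gene was read in every sample first. ASK1 (AT1G75950) lies on chromosome 1 at 28516519 to 28517896 in TAIR10.1. Its level was 19.6 ± 13.4 CPM (SD, n = 2) in ask1 buds against 248.8 ± 1.85 in ASK1 WT buds and 257.2 ± 0.903 in Col-0 buds. In open flowers it was 40.3 ± 15.1 CPM in ask1, 293.8 ± 7.28 in ASK1 WT and 308.6 ± 2.35 in Col-0. The individual ask1 libraries held 10.1 and 29.1 CPM in buds and 50.9 and 29.6 CPM in open flowers, all far below every control library. The fall against ASK1 WT was -3.68 ± 0.41 in buds (12.8-fold, edgeR Benjamini-Hochberg adjusted p = 7.77e-05) and -2.87 ± 0.39 in open flowers (7.30-fold, adjusted p = 3.80e-04). Against Col-0 it was -3.72 ± 0.41 and -2.94 ± 0.39. The nearest relative, ASK2 (AT5G42190), did not change in ask1 buds (0.04 ± 0.16) or open flowers (0.38 ± 0.16). The cullin CUL1 (AT4G02570) and the hormone-receptor F-box genes TIR1 (AT3G62980) and COI1 (AT2G39940) did not change either, at 0.00 ± 0.16, 0.36 ± 0.20 and -0.09 ± 0.16 in buds and -0.25 ± 0.16, -0.06 ± 0.20 and -0.26 ± 0.16 in open flowers. Without ask1 flower replicate 2, the open-flower values against ASK1 WT lay further from 0, at 0.63 for ASK2, -0.51 for CUL1, -0.46 for TIR1 and -0.57 for COI1. These values rest on replicate 1 alone, in which levels fell with exon length (rank correlation -0.467), so they were not read as changes of these genes.

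**Figure D1:**
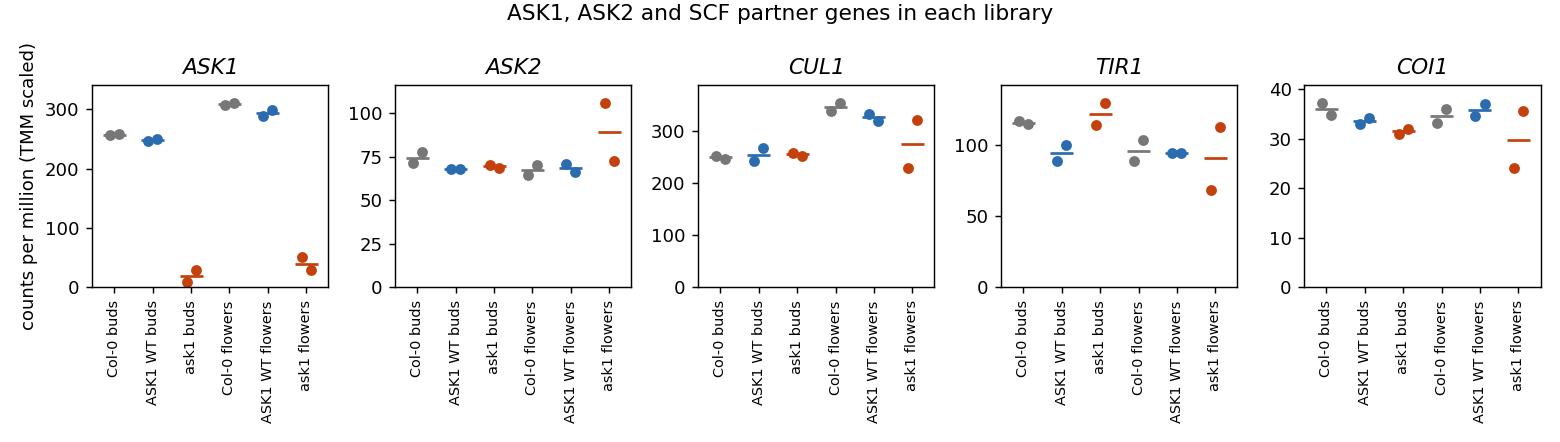
TMM-scaled CPM (vertical axes, from 0) of ASK1, ASK2, CUL1, TIR1 and COI1 (1 panel each) in every library (points) of the 6 groups (horizontal axis), with lines at the group means. For ASK1 the 4 ask1 libraries lie between 10.1 and 50.9 CPM and the control group means between 248.8 and 308.6 CPM. Replicate 1 of ask1 open flowers is the highest library for ASK2 and the lowest for CUL1, TIR1 and COI1.

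The comparison of ask1 with ASK1 WT buds asked which transcripts differed in ask1 while flowers were forming. The deepest falls in ask1 buds included genes of pollen signalling. The serine carboxypeptidase-like gene scpl38 (AT2G05850) fell 147-fold with a 95% interval of 50.1 to 717 in counts. The acyl-activating enzyme gene AAE11 (AT1G66120), the pollen receptor kinase gene PRK5 (AT1G50610) and the gene of the signal peptide RALFL25 (AT3G25165) stood at -7.25 ± 0.37, -6.63 ± 0.45 and -6.12 ± 0.45. The blue-light receptor F-box gene FKF1 (AT1G68050) rose by 4.28 ± 0.30 and the cold-regulated gene COR27 (AT5G42900) rose by 4.27 ± 0.33. TI1 (AT2G43510), a trypsin inhibitor gene, rose by 5.91 ± 0.46 (edgeR Benjamini-Hochberg adjusted p = 9.98e-06), and RbcX1 (AT4G04330), which encodes a Rubisco assembly chaperone, rose by 4.38 ± 0.42. Of 21890 tested genes, 1934 rose and 3727 fell in ask1 buds. Further genes with the largest rises against both controls were the extensin gene EXT4 (AT1G76930) at 3.92 ± 0.64, HR4 (AT3G50480) at 4.15 ± 0.33, IGMT5 (AT1G76790) at 4.81 ± 0.39 and IGMT4 (AT1G21130), whose counts rose 208-fold with a 95% interval of 36.9 to 8251. Further large falls were those of GH9B11 (AT2G44560) at -6.22 ± 0.27, COBL11 (AT4G27110) at -5.97 ± 0.43, DAZ3 (AT4G35700) at -5.62 ± 0.48, NRAMP5 (AT4G18790), 94.9-fold with a 95% interval of 32.2 to 463, and RABH1d (AT2G22290), 46.7-fold with a 95% interval of 7.99 to 1881. Counts of LCR4 (AT3G25265) fell 72.4-fold with a 95% interval of 19.7 to 603. RRTF1 (AT4G34410) and WRKY40 (AT1G80840) also rose, by 6.42 ± 1.64 and 4.47 ± 1.11, and were less even. RRTF1 lost its call without ask1 bud replicate 2 (3.05), ASK1 WT bud replicate 1 (6.18) or ASK1 WT bud replicate 2 (6.79), and WRKY40 did so without the same libraries (1.69, 4.12 and 5.04).

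Some of these values moved with single libraries. PRK5 was at -10.81 without ask1 bud replicate 2, and LCR4 was at -9.30 without ask1 bud replicate 1. The number of changed genes in buds was 3765 without ask1 bud replicate 1, 3399 without ASK1 WT bud replicate 1 and 3572 without ASK1 WT bud replicate 2, against 5661 with all libraries. The balance of rises and falls was 3464 and 4101 in a fit of only the libraries compared, 3754 and 4317 without ask1 bud replicate 2 and ask1 flower replicate 1, and 651 and 2346 at 2-fold or more. FKF1, RbcX1, IGMT5, RRTF1 and WRKY40 overlap genes on the opposite strand, and IGMT4 and IGMT5 are close paralogs, so their values are uncertain because the counting strand was not given in the sources used here. Intervals and floors throughout cover counting error only.

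**Figure D2:**
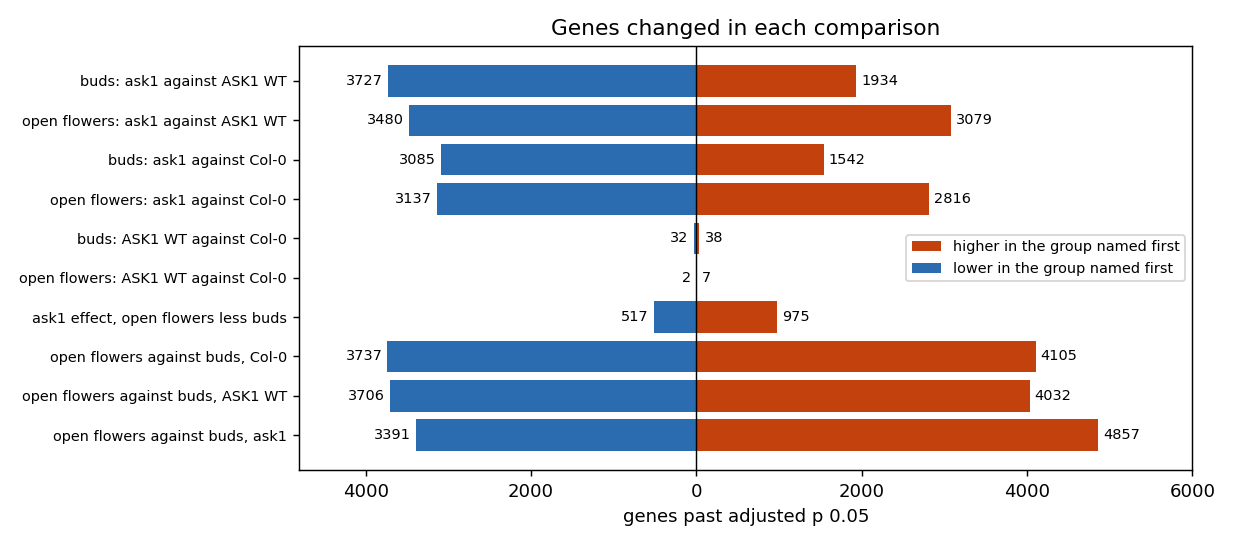
Number of genes (horizontal axis) higher or lower at a Benjamini-Hochberg adjusted edgeR p under 0.05 in each comparison (vertical axis), with bars to the right for genes higher and to the left for genes lower in the group named first. Buds of ask1 against ASK1 WT give 1934 higher and 3727 lower genes, open flowers give 3079 and 3480, and ASK1 WT against Col-0 gives 70 changed genes in buds and 9 in open flowers.

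Pollen genes formed the most complete loss in ask1 buds. Of 42 tested genes of mature pollen and the pollen tube, 39 fell and 3 did neither (39 falling when adjusted over the list alone). The sugar transporter gene STP11 (AT5G23270) was at -5.93 ± 0.45, the receptor kinase gene ANX2 (AT5G28680) at -5.18 ± 0.34 and the calcium-dependent kinase genes CPK34 (AT5G19360) and CPK17 (AT5G12180) at -5.14 ± 0.39 and -5.08 ± 0.39. The list median was -3.86 (-3.82 with genes at 0 counts in a group set to their bound), with limma camera adjusted p = 1.08e-21 and estimated-correlation adjusted p = 0.449. Tapetum and pollen-wall genes fell in part. Of 38 tested, 1 rose, 13 fell and 24 did neither (1 rising and 14 falling when adjusted over the list alone), including the callose synthase gene CALS5 (AT2G13680) at -3.26 ± 0.40, the extracellular lipase genes EXL6 (AT1G75930) and EXL4 (AT1G75910) at -2.33 ± 0.20 and -1.27 ± 0.18, and RPG1 (AT5G40260) at -1.45 ± 0.23 (list adjusted p = 0.111 and estimated-correlation adjusted p = 0.449). Of 29 meiosis genes, 2 fell and 27 did neither (2 falling when adjusted over the list alone). The meiotic cohesin gene SYN1 (AT5G05490) was one of them, at -2.12 ± 0.34, and the list did not pass (adjusted p = 0.962 and estimated-correlation adjusted p = 0.977). The list of floral organ identity and meristem genes did not move as a whole either. Of 20, 1 rose, 6 fell and 13 did neither (1 rising and 6 falling when adjusted over the list alone), with CAL (AT1G26310) at 1.298 ± 0.21, a median of -0.03, a mean of -0.15 and a list test pointing upward (adjusted p = 0.962 and estimated-correlation adjusted p = 0.977). Of 8 seed and embryo genes, 3 fell and 5 did neither (3 falling when adjusted over the list alone), with a median of -1.195 (-0.93 with genes at 0 counts in a group set to their bound) and adjusted p = 0.237 and estimated-correlation adjusted p = 0.618. CPK34 and SYN1 overlap opposite-strand genes and are uncertain.

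Hormone-related genes moved in both directions in ask1 buds. Of 42 jasmonate genes, 19 rose, 9 fell and 14 did neither (20 rising and 9 falling when adjusted over the list alone), with a median of 0.45 and limma camera adjusted p = 0.00465 and estimated-correlation adjusted p = 0.561. Among those that fell were the stamen MYB genes MYB57 (AT3G01530) (-5.43 ± 0.51) and MYB108 (AT3G06490) (-3.37 ± 0.31) and the jasmonate oxidase gene JOX4 (AT2G38240) (-3.88 ± 0.43). Of 21 SAUR and GH3 genes induced by auxin, 10 fell and 11 did neither (12 falling when adjusted over the list alone), including SAUR64 (AT1G29450) at -2.73 ± 0.50. Their median was -1.66 (-1.49 with genes at 0 counts in a group set to their bound), with limma camera adjusted p = 9.13e-04 and estimated-correlation adjusted p = 0.580. Of 26 Aux/IAA genes, 4 rose, 9 fell and 13 did neither (4 rising and 14 falling when adjusted over the list alone), with IAA14 (AT4G14550) at -3.51 ± 0.33 and IAA19 (AT3G15540) at -3.49 ± 0.38 (list adjusted p = 0.0947 and estimated-correlation adjusted p = 0.757). Without ask1 flower replicate 1, 4 rose and 15 fell and the Aux/IAA list passed (adjusted p = 0.0309). Of 22 gibberellin genes, 4 rose, 5 fell and 13 did neither (4 rising and 5 falling when adjusted over the list alone). GA2OX8 (AT4G21200) and GA3OX3 (AT4G21690), which encode gibberellin oxidases, were at -3.81 ± 0.48 and -3.48 ± 0.62, and the receptor gene GID1A (AT3G05120) was at 1.08 ± 0.13. The gibberellin median was -0.06 (-0.11 with genes at 0 counts in a group set to their bound), its mean was -0.34 and its test pointed upward (adjusted p = 0.962 and estimated-correlation adjusted p = 0.977). Of 14 ethylene genes, 2 rose, 1 fell and 11 did neither (1 rising and 0 falling when adjusted over the list alone), with list adjusted p = 0.291 and estimated-correlation adjusted p = 0.757. Of 18 salicylate and defence genes, 6 rose, 2 fell and 10 did neither (6 rising and 2 falling when adjusted over the list alone), with PR4 (AT3G04720) at 3.89 ± 0.46 (list adjusted p = 0.0823 and estimated-correlation adjusted p = 0.726). MYB57 and SAUR64 overlap opposite-strand genes, and SAUR64 has close paralogs, so both are uncertain.

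Nearly every clock gene changed in ask1 buds, in a direction that depended on the gene. Of 17 tested, 7 rose, 9 fell and 1 did neither (8 rising and 9 falling when adjusted over the list alone). The pseudo-response regulator gene PRR5 (AT5G24470) rose by 3.502 ± 0.17, and the morning-expressed genes LHY (AT1G01060), CCA1 (AT2G46830) and RVE8 (AT3G09600) were at -2.85 ± 0.18, -2.68 ± 0.17 and -2.84 ± 0.19. The list as a whole did not pass (adjusted p = 0.692 and estimated-correlation adjusted p = 0.977). Of 27 photosynthesis genes, 4 rose and 23 did neither (4 rising when adjusted over the list alone), with a median of 0.29 and limma camera adjusted p = 0.00345 and estimated-correlation adjusted p = 0.743. The number rising was 7 with the length trend removed and 17 without ask1 flower replicate 1, which shared the fitted spread (adjusted p = 0.00110). One of them was LHCB1.3 (AT1G29930) at 1.08 ± 0.16, a close paralog of other LHCB1 genes with an opposite-strand overlap and therefore uncertain. Of 15 flavonoid genes, 4 fell and 11 did neither (4 falling when adjusted over the list alone), with TT7 (AT5G07990) at -1.04 ± 0.18 and TT19 (AT5G17220) at -1.57 ± 0.25 (list adjusted p = 0.0545 and estimated-correlation adjusted p = 0.618). Of 25 cell-cycle genes, 1 fell and 24 did neither (none when adjusted over the list alone), with a median of -0.05, a mean of -0.04 and an upward test (adjusted p = 0.818 and estimated-correlation adjusted p = 0.977). Of 12 heat-shock genes, 1 rose, 3 fell and 8 did neither (1 rising and 4 falling when adjusted over the list alone), with HSP70 (AT3G12580) at -1.28 ± 0.19, a median of -0.09, a mean of -0.01 and an upward test (adjusted p = 0.962 and estimated-correlation adjusted p = 0.977). Of 12 senescence genes, 3 rose, 2 fell and 7 did neither (5 rising and 2 falling when adjusted over the list alone), with BFN1 (AT1G11190) at -0.82 ± 0.15, a median of 0.20 (0.26 with genes at 0 counts in a group set to their bound) and adjusted p = 0.291 and estimated-correlation adjusted p = 0.743.

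Genes of the SCF pathway itself gave mixed changes in ask1 buds. Of 12 tested ASK family genes, 1 fell and 11 did neither (1 falling when adjusted over the list alone), the 1 being ASK1, with a list median of -0.35 (-0.37 with genes at 0 counts in a group set to their bound) and adjusted p = 0.204 and estimated-correlation adjusted p = 0.580. Of 27 SCF partners and studied F-box genes, 5 rose, 1 fell and 21 did neither (5 rising and 1 falling when adjusted over the list alone), with FKF1 rising, KMD4 (AT3G59940) at 1.296 ± 0.18 and the auxin-receptor gene AFB1 (AT4G03190) at -1.24 ± 0.13 (list adjusted p = 0.111 and estimated-correlation adjusted p = 0.743). None of 51 genes of the 26S proteasome passed the edgeR test, 0 had an unadjusted p under 0.05 and 0 passed DESeq2 (list adjusted p = 0.237 and estimated-correlation adjusted p = 0.977). Without ask1 flower replicate 1, which shared the fitted spread, 6 of them rose, 1 fell and the list passed (adjusted p = 0.0317). Of 276 F-box genes named by the annotation, 7 rose, 46 fell and 223 did neither (7 rising and 42 falling when adjusted over the list alone), with a median of -0.33 and limma camera adjusted p = 0.00465 and estimated-correlation adjusted p = 0.449. The F-box list did not pass without the low-count filter (adjusted p = 0.143). The lowest included AT2G26850 at -5.44 ± 0.40 and AT1G80470 at -5.04 ± 0.36. Without ask1 bud replicate 1, the SCF (adjusted p = 0.0448), salicylate and defence (adjusted p = 0.00498) and flavonoid (adjusted p = 0.0430) lists passed, and the flavonoid list also passed without ask1 flower replicate 1 (adjusted p = 0.0298), with RLE factors (adjusted p = 0.0487) and without the low-count filter (adjusted p = 0.0294). KMD4, AFB1, TT19 and AT1G80470 overlap opposite-strand genes and are uncertain.

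**Figure D3:**
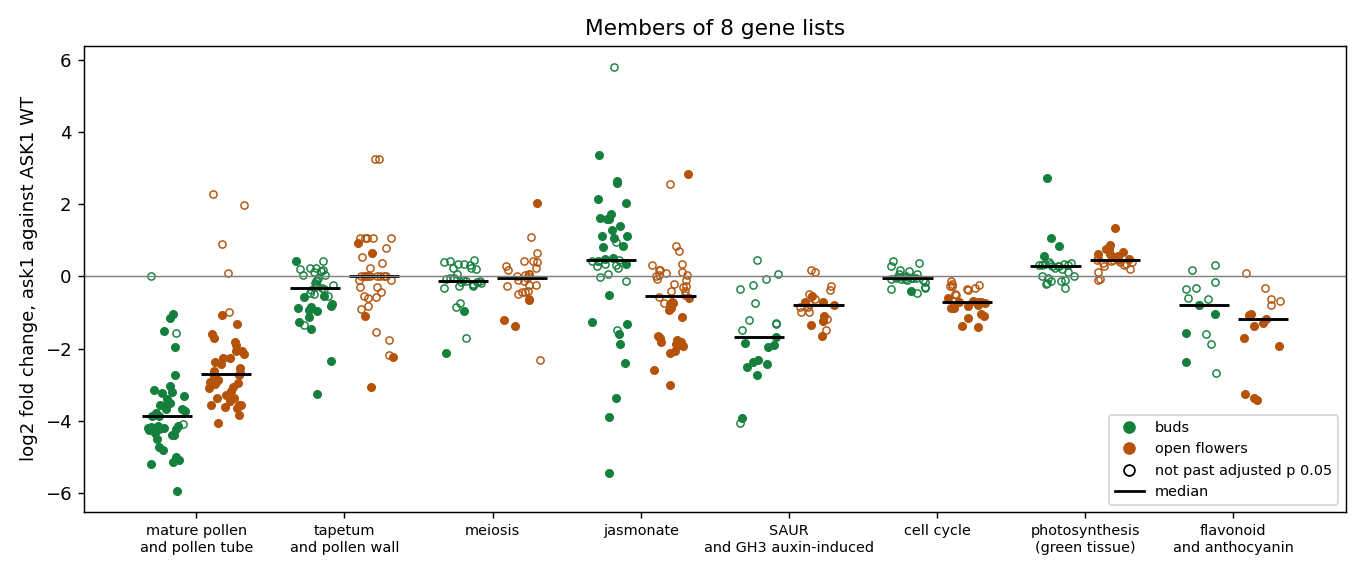
Log2 fold change of ask1 against ASK1 WT (vertical axis) for each tested gene (points, filled where the adjusted edgeR p was under 0.05) of 8 gene lists (horizontal axis) in buds and open flowers, with lines at the list medians. The pollen list lies lowest, with medians of -3.86 in buds and -2.71 in open flowers.

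The comparison of ask1 with ASK1 WT open flowers asked the same question at a later stage. FKF1, COR27 and RbcX1 were again among the largest rises, at 5.21 ± 0.31, 4.79 ± 0.35 and 4.88 ± 0.49, and the clock gene PRR3 (AT5G60100) rose by 3.82 ± 0.51. Expansin genes were among those that fell furthest. Counts of EXPA22 (AT5G39270) fell 90.9-fold with a 95% interval of 16.0 to 3623, those of scpl21 (AT3G25420) fell 85.5-fold with a 95% interval of 23.4 to 711, and sks8 (AT1G21850) and EXPA25 (AT5G39300) were at -6.33 ± 0.60 and -5.42 ± 0.49. BAS (AT1G78950) was at -5.10 ± 0.25 (edgeR Benjamini-Hochberg adjusted p = 1.21e-06). Of 21890 tested genes, 3079 rose and 3480 fell. Other large rises were those of PCR1 (AT1G14880) at 3.99 ± 0.51, the glucanase gene BG3 (AT3G57240) at 3.90 ± 0.45, PLA2A (AT2G26560) at 4.18 ± 0.62, IGMT4 at 5.06 ± 0.67, CCOAMT (AT1G67980) at 4.12 ± 0.81 and that of PXMT1 (AT1G66700), which was 60.5-fold with a 95% interval of 20.3 to 297 in counts. Other large falls, given in counts, were those of XTH1 (AT4G13080) (at least 30.6-fold), LCR60 (AT2G20208) (133-fold with a 95% interval of 23.5 to 5288), SCRL10 (AT4G15735) (112-fold with a 95% interval of 30.6 to 926) and EXPB4 (AT2G45110) (49.9-fold with a 95% interval of 16.8 to 244). LCR60 overlaps an opposite-strand gene and is uncertain. DDF1 (AT1G12610) stood at -5.37 ± 0.97 and lost its call without either ask1 flower replicate (-5.78 without replicate 1 and -5.05 without replicate 2).

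Some of the open-flower values also depended on single libraries. CCOAMT was at 2.70 and EXPB4 at -9.34 without ask1 flower replicate 2, and PXMT1 was at 9.27 without ASK1 WT flower replicate 2. The number of changed genes was 11550 without ask1 flower replicate 2, 3159 without ASK1 WT flower replicate 1 and 3671 without ASK1 WT flower replicate 2, against 6559 with all libraries. The balance of rises and falls also varied, from 3981 and 3681 with the length trend removed to 2234 and 3861 without the low-count filter, 2714 and 4629 without ask1 flower replicate 1, 568 and 1541 in a fit of only the libraries compared and 888 and 1983 at 2-fold or more. The ask1 flower pair correlated at 0.970 with 2683 genes over 2-fold apart, the ask1 bud pair at 0.984 with 1312, and the control pairs at 0.991 to 0.993 with 424 to 588. In ask1 flower replicate 1, levels fell with exon length at a rank correlation of -0.467 across genes, whereas the other libraries lay between -0.0724 and 0.0753. Its median difference from the controls was 0.50 for genes up to 1239 bp and -0.56 for genes of at least 2363 bp, against 0.00 and 0.01 in replicate 2.

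**Figure D4:**
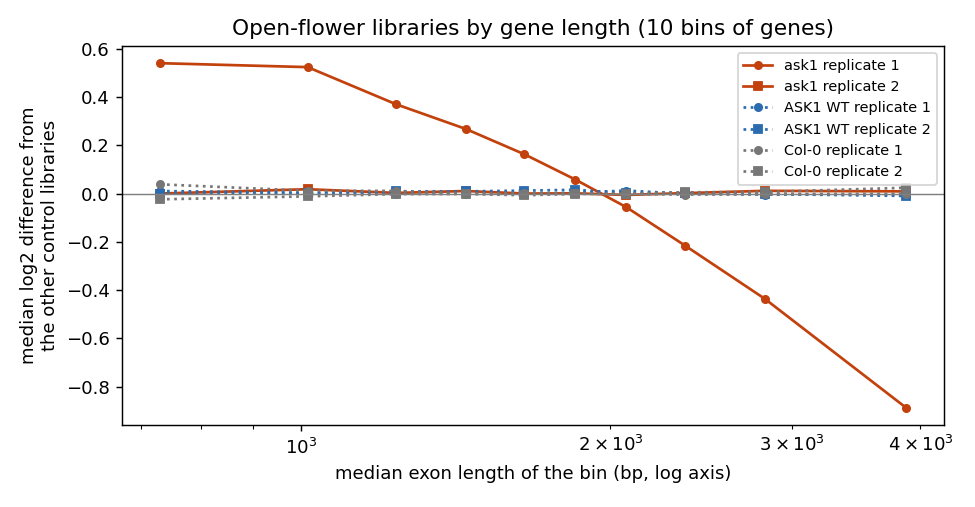
Median log2 difference of each open-flower library (lines) from the control libraries other than itself (vertical axis) in 10 bins of genes by exon length (horizontal axis, bp, log scale). The line of ask1 flower replicate 1 falls with length, from 0.54 in the first bin to -0.89 in the last.

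Pollen genes were low in ask1 open flowers as well. Of 42 tested, 37 fell and 5 did neither (2 rising and 38 falling when adjusted over the list alone), with PRK6 (AT5G20690) at -4.07 ± 0.24, PRK2 (AT2G07040) at -3.62 ± 0.51, CPK34 at -3.84 ± 0.27 and the calcium pump gene ACA9 (AT3G21180) at -3.64 ± 0.31. The list median was -2.71 (limma camera adjusted p = 1.81e-14 and estimated-correlation adjusted p = 0.476). Cell-cycle genes, of which few changed in buds, fell here. Of 25, 15 fell and 10 did neither (15 falling when adjusted over the list alone), including AUR2 (AT2G25880) at -1.36 ± 0.22, MCM6 (AT5G44635) at -1.14 ± 0.16 and HIK (AT1G18370) at -1.09 ± 0.13, with a median of -0.69 and limma camera adjusted p = 5.72e-07 and estimated-correlation adjusted p = 0.414. Of 15 flavonoid genes, 10 fell and 5 did neither (11 falling when adjusted over the list alone), with LDOX (AT4G22880) at -3.35 ± 0.38, DFR (AT5G42800) at -3.25 ± 0.47, UF3GT (AT5G54060) at -3.43 ± 0.54 and TT19 at -1.91 ± 0.22, a median of -1.17 and limma camera adjusted p = 1.43e-04 and estimated-correlation adjusted p = 0.435. Of 8 seed and embryo genes, 4 fell and 4 did neither (4 falling when adjusted over the list alone), with BAN (AT1G61720) at -2.45 ± 0.31 and PHE1 (AT1G65330) falling 27.3-fold with a 95% interval of 9.07 to 135, a median of -1.89 and limma camera adjusted p = 0.00843 and estimated-correlation adjusted p = 0.414. The seed list no longer passed without ask1 flower replicate 1 (adjusted p = 0.0553) or replicate 2 (adjusted p = 0.114), nor without the low-count filter (adjusted p = 0.130). PHE1 was at -8.48 without ask1 flower replicate 1. Of 38 tapetum and pollen-wall genes, 2 rose, 3 fell and 33 did neither (2 rising and 3 falling when adjusted over the list alone), with a median of 0.00 (-0.11 with genes at 0 counts in a group set to their bound), a mean of -0.03 and adjusted p = 0.988 and estimated-correlation adjusted p = 0.993. Of 29 meiosis genes, 1 rose, 3 fell and 25 did neither (0 rising and 2 falling when adjusted over the list alone), with list adjusted p = 0.797 and estimated-correlation adjusted p = 0.973. Of 20 floral organ identity and meristem genes, 4 rose, 3 fell and 13 did neither (4 rising and 3 falling when adjusted over the list alone), with CAL at 1.68 ± 0.22, AP1 (AT1G69120) at 0.95 ± 0.16 and RBE (AT5G06070) at -3.37 ± 0.62. That list had a median of 0.11 (0.13 with genes at 0 counts in a group set to their bound), a mean of -0.37 and an upward test (adjusted p = 0.455 and estimated-correlation adjusted p = 0.893). ACA9, AUR2 and TT19 overlap opposite-strand genes and are uncertain.

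Jasmonate genes in ask1 open flowers went the other way from buds. Of 42, 1 rose, 19 fell and 22 did neither (4 rising and 19 falling when adjusted over the list alone), with JRG21 (AT3G55970) at -2.11 ± 0.21 and MYB24 (AT5G40350) rising by 2.85 ± 0.22, a median of -0.54 and limma camera adjusted p = 0.00554 and estimated-correlation adjusted p = 0.511. Of 21 SAUR and GH3 genes, 8 fell and 13 did neither (8 falling when adjusted over the list alone), with GH3.5 (AT4G27260) at -1.34 ± 0.21, a median of -0.79 and limma camera adjusted p = 0.00124 and estimated-correlation adjusted p = 0.588. Without ask1 flower replicate 2 neither list passed, but that left only replicate 1, whose levels fell with exon length. The median exon length of the SAUR and GH3 genes was 895 bp. With the length trend removed both lists passed (limma camera adjusted p = 0.00451 for jasmonate and 1.91e-05 for SAUR and GH3). Then 2 jasmonate genes rose and 18 fell, and 13 SAUR and GH3 genes fell. Of 26 Aux/IAA genes, 3 rose, 9 fell and 14 did neither (3 rising and 10 falling when adjusted over the list alone), with IAA31 (AT3G17600) at -4.61 ± 0.64 and IAA14 at -1.46 ± 0.22 (list adjusted p = 0.126 and estimated-correlation adjusted p = 0.893). The Aux/IAA list passed with the length trend removed (adjusted p = 0.0209) and without ask1 flower replicate 1, where 14 fell (adjusted p = 0.00472). Of 22 gibberellin genes, 6 rose, 6 fell and 10 did neither (6 rising and 6 falling when adjusted over the list alone), with GA2OX8 at -2.86 ± 0.48 and GASA4 (AT5G15230) at 1.27 ± 0.21 (list adjusted p = 0.988 and estimated-correlation adjusted p = 0.993). Of 14 ethylene genes, 4 fell and 10 did neither (4 falling when adjusted over the list alone), with EIL1 (AT2G27050) at -0.88 ± 0.13 (list adjusted p = 0.353 and estimated-correlation adjusted p = 0.893). Of 18 salicylate and defence genes, 2 rose, 5 fell and 11 did neither (2 rising and 5 falling when adjusted over the list alone). PR1 (AT2G14610) fell at least 12.9-fold, the glucanase gene PR2 (AT3G57260) was at -2.51 ± 0.39 and PR5 (AT1G75040) rose by 2.17 ± 0.14 (list adjusted p = 0.455 and estimated-correlation adjusted p = 0.893). Of 12 senescence genes, 1 rose, 6 fell and 5 did neither (1 rising and 7 falling when adjusted over the list alone), with SAG12 (AT5G45890) at -3.52 ± 0.52 and NYE1 (AT4G22920) at -1.27 ± 0.15 (list adjusted p = 0.0641 and estimated-correlation adjusted p = 0.528). The senescence list passed with the length trend removed (adjusted p = 0.0209) and without ASK1 WT flower replicate 1 (adjusted p = 0.0249). MYB24 overlaps an opposite-strand gene and is uncertain.

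Photosynthesis and clock genes changed in ask1 open flowers too. Of 27 photosynthesis genes, 12 rose and 15 did neither (15 rising when adjusted over the list alone), with a median of 0.47 and limma camera adjusted p = 3.41e-05 and estimated-correlation adjusted p = 0.790. Their median exon length was 1312 bp, and the result depended on the library biased by length. The median was 0.26 with the length trend removed (adjusted p = 0.00106), and 8 rose and 3 fell without ask1 flower replicate 1 (adjusted p = 0.0309). Of 17 clock genes, 8 rose, 6 fell and 3 did neither (8 rising and 6 falling when adjusted over the list alone), with PRR5 at 3.998 ± 0.17 and ELF4 (AT2G40080) at 3.65 ± 0.32 (list adjusted p = 0.455 and estimated-correlation adjusted p = 0.893). In both tissues 13 of the 17 clock genes changed in the same direction. The 7 that rose were TOC1 (AT5G61380) at 1.64 ± 0.25 in buds and 1.46 ± 0.25 in open flowers, PRR3, PRR5, GI (AT1G22770), ELF3 (AT2G25930), ELF4 and LUX (AT3G46640). The 6 that fell were CCA1, LHY, PRR9 (AT2G46790), RVE8, LNK1 (AT5G64170) and LNK2 (AT3G54500). BOA (AT5G59570) fell in buds (-1.37 ± 0.26) and rose in open flowers (2.42 ± 0.32). ELF3, LUX, LNK1, LNK2 and BOA overlap opposite-strand genes and are uncertain.

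**Figure D5:**
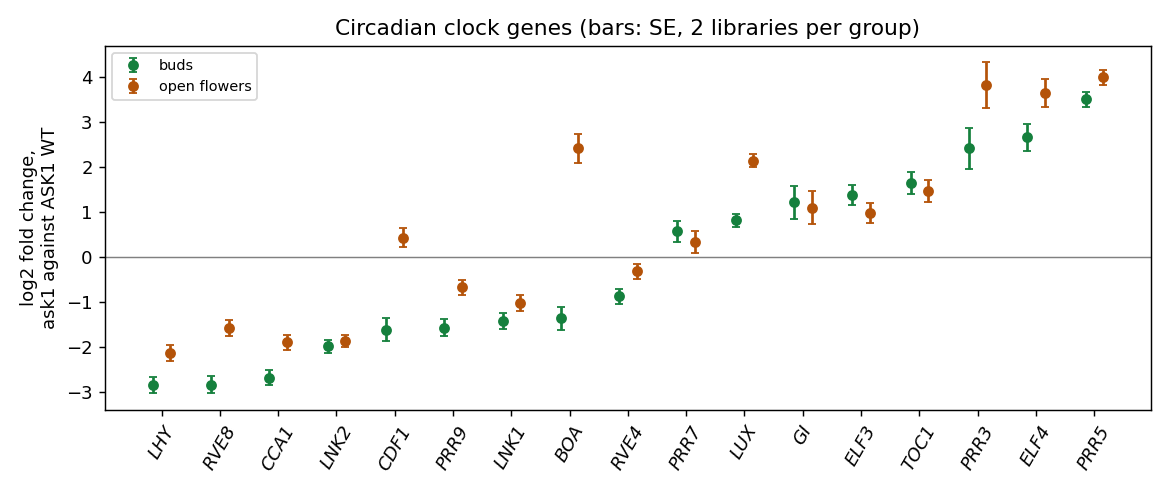
Log2 fold change of ask1 against ASK1 WT (vertical axis) of the 17 tested clock genes (horizontal axis) in buds and open flowers, with points for the edgeR estimates and bars for 1 SE. PRR5 lies at 3.502 and 3.998, CCA1 at -2.68 and -1.90, and BOA at -1.37 and 2.42.

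Genes of the SCF pathway in ask1 open flowers also gave mixed changes. Of 12 ASK family genes, 1 rose, 3 fell and 8 did neither (1 rising and 3 falling when adjusted over the list alone), with ASK3 (AT2G25700) falling 24.4-fold with a 95% interval of 6.46 to 206. The median of that list was 0.16 (-0.11 with genes at 0 counts in a group set to their bound), its mean was -0.25 and its test pointed downward (adjusted p = 0.902 and estimated-correlation adjusted p = 0.956). ASK3 was at -7.74 without ask1 flower replicate 1. Of 27 SCF partners and studied F-box genes, 7 rose, 1 fell and 19 did neither (7 rising and 1 falling when adjusted over the list alone), with KMD1 (AT1G80440) at 2.41 ± 0.33 and KMD4 at 0.91 ± 0.17 (list adjusted p = 0.353 and estimated-correlation adjusted p = 0.893). The SCF list passed with the length trend removed (adjusted p = 0.0361) and without ask1 flower replicate 1 (adjusted p = 0.0309). Of 51 genes of the 26S proteasome, 6 rose and 45 did neither (none when adjusted over the list alone), with a median of 0.18 and limma camera adjusted p = 0.0484 and estimated-correlation adjusted p = 0.893. That list passed narrowly. It did not pass with the length trend removed (adjusted p = 0.116), with RLE factors (adjusted p = 0.0637) or without the low-count filter (adjusted p = 0.0934). Nor did it pass without ask1 flower replicate 1, where it pointed downward with 2 rising and 9 falling (adjusted p = 0.382), without ASK1 WT flower replicate 1 (adjusted p = 0.0537) or without ASK1 WT flower replicate 2 (adjusted p = 0.136). Of 276 F-box genes, 16 rose, 27 fell and 233 did neither (12 rising and 24 falling when adjusted over the list alone), with a median of 0.00 (0.10 with genes at 0 counts in a group set to their bound), a mean of -0.34 and an upward test (adjusted p = 0.988 and estimated-correlation adjusted p = 0.993). AT1G76830 fell at least 7.99-fold. Of 12 heat-shock genes, 1 fell and 11 did neither (none when adjusted over the list alone), with list adjusted p = 0.988 and estimated-correlation adjusted p = 0.993.

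Both tissues were then set side by side to ask which changes they shared. In ask1, 914 genes rose and 1818 fell in both tissues, against 272 and 593 expected for independent sets (one-sided Fisher's exact test, odds ratios 7.36 and 9.45, p = 6.34e-307 for the rises and a smaller p for the falls). FKF1, COR27, RbcX1 and PRR5 were among the shared rises, and CPK34 (-5.14 ± 0.39 in buds and -3.84 ± 0.27 in open flowers), IAA14 (-3.51 ± 0.33 and -1.46 ± 0.22) and GA2OX8 (-3.81 ± 0.48 and -2.86 ± 0.48) were among the shared falls. Only 64 genes rose in buds and fell in open flowers, and 109 did the reverse. The log2 fold changes correlated across genes at r = 0.45. The shared set held 4101 genes without ask1 flower replicate 1, 4348 without ask1 flower replicate 2 and 1772 without ASK1 WT flower replicate 1, against 2732 with all libraries.

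The comparison with Col-0 asked whether the same changes appeared against the standard accession. ASK1, FKF1, COR27 and TI1 again stood out in buds, at -3.72 ± 0.41, 4.37 ± 0.30, 4.01 ± 0.32 and 5.79 ± 0.46, and in open flowers FKF1, COR27 and BAS were at 4.31 ± 0.29, 4.41 ± 0.35 and -4.996 ± 0.25. In buds 1542 genes rose and 3085 fell, and in open flowers 2816 rose and 3137 fell. Against both controls in the same direction, 1231 genes rose and 2762 fell in buds and 2308 rose and 2808 fell in open flowers, with 0 in opposite directions. In 20 simulations with no ask1 effect, at most 3 genes passed a comparison, and at most 0 in buds and 1 in open flowers passed both. So few could not show how far error in the shared ask1 libraries fed the overlap. That error also fed the correlation, which was 0.930 in buds and 0.911 in open flowers against 0.513 and 0.517 in the simulations.

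By list, pollen genes fell against Col-0 in both tissues. Of 42, 39 fell in buds (40 adjusted over the list alone), with a median of -3.65 (-3.67 with genes at 0 counts in a group set to their bound) and limma camera adjusted p = 1.70e-23 and estimated-correlation adjusted p = 0.440. In open flowers 37 fell and 1 rose (38 and 2 adjusted over the list alone), with a median of -2.85 and adjusted p = 4.62e-17 and estimated-correlation adjusted p = 0.373. The test of SAUR and GH3 genes pointed downward, with 11 of 21 falling in buds (adjusted p = 1.53e-04 and estimated-correlation adjusted p = 0.579) and 7 in open flowers (adjusted p = 0.00161 and estimated-correlation adjusted p = 0.548). That of photosynthesis genes pointed upward, with only 4 of 27 rising in buds (adjusted p = 0.00653 and estimated-correlation adjusted p = 0.734) and 11 in open flowers (adjusted p = 2.37e-05 and estimated-correlation adjusted p = 0.686). The jasmonate test pointed upward in buds, with 16 of 42 rising and 10 falling (adjusted p = 0.0189 and estimated-correlation adjusted p = 0.579), and downward in open flowers, with 1 rising and 23 falling (adjusted p = 2.72e-05 and estimated-correlation adjusted p = 0.357). In buds the F-box test pointed downward, with 6 of 276 rising and 42 falling (adjusted p = 0.00204 and estimated-correlation adjusted p = 0.381), and the salicylate and defence test upward, with 6 of 18 rising and 2 falling (adjusted p = 0.00691 and estimated-correlation adjusted p = 0.579). In open flowers the tests of the cell cycle (13 of 25 falling, adjusted p = 4.85e-06 and estimated-correlation adjusted p = 0.357), flavonoids (9 of 15, adjusted p = 0.00124 and estimated-correlation adjusted p = 0.403), seed genes (4 of 8, adjusted p = 0.0271 and estimated-correlation adjusted p = 0.357) and ethylene (6 of 14, with 1 rising, adjusted p = 0.0224 and estimated-correlation adjusted p = 0.548) pointed downward, and the 26S proteasome list did not pass (adjusted p = 0.0787 and estimated-correlation adjusted p = 0.913).

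Leaving out single libraries changed several of these list results. In buds, jasmonate did not pass without ask1 bud replicate 2, Col-0 bud replicate 2 or ask1 flower replicate 1, nor photosynthesis without Col-0 bud replicate 2. In open flowers, ethylene and seed did not pass without ask1 flower replicate 1, nor SAUR and GH3, seed and flavonoid without ask1 flower replicate 2, nor seed without Col-0 flower replicate 2. With the length trend removed, SAUR and GH3, seed, flavonoid and ethylene passed in open flowers (limma camera adjusted p = 1.35e-05, 0.0138, 1.40e-04 and 0.0284). Other lists did not pass in the main test but did so under alternatives. Aux/IAA genes did so in buds with RLE factors (adjusted p = 0.0486), without the low-count filter (adjusted p = 0.0379), without ask1 bud replicate 2 (adjusted p = 0.0265), Col-0 bud replicate 2 (adjusted p = 0.0197) or ask1 flower replicate 1 (adjusted p = 0.0214) and in open flowers with the length trend removed (adjusted p = 0.0318) or without ask1 flower replicate 1 (adjusted p = 0.00711). The 26S proteasome did so in buds without ask1 flower replicate 1, with 7 rising (adjusted p = 0.0138). In open flowers the clock did so without ask1 flower replicate 1 (adjusted p = 0.0477), the 26S proteasome without ask1 flower replicate 2 (adjusted p = 4.61e-06) and senescence without Col-0 flower replicate 2 (adjusted p = 0.0238), without the low-count filter (adjusted p = 0.0351) or with the length trend removed (adjusted p = 0.0138). Without the low-count filter the F-box list did not pass in buds (adjusted p = 0.143) nor the seed list in open flowers (adjusted p = 0.284). The number of changed genes against Col-0 was 2844 in buds without ask1 bud replicate 1, 2912 without Col-0 bud replicate 1 and 2559 without Col-0 bud replicate 2. In open flowers it was 11247 without ask1 flower replicate 2, 2933 without Col-0 flower replicate 1 and 2882 without Col-0 flower replicate 2. Against both controls, buds gave 2572 genes without ask1 bud replicate 1 and 2453 without Col-0 bud replicate 2. Open flowers gave 10195 without ask1 flower replicate 2, 2862 without ASK1 WT flower replicate 1, 3191 without ASK1 WT flower replicate 2, 2773 without Col-0 flower replicate 1 and 2778 without Col-0 flower replicate 2.

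ASK1 WT was compared with Col-0 to ask how far the controls differed from each other. The flowering-time MADS gene MAF5 (AT5G65080) was the clearest difference, lower in ASK1 WT, at -5.33 ± 0.35 in open flowers (40.2-fold, edgeR Benjamini-Hochberg adjusted p = 2.81e-04) and -3.03 ± 0.28 in buds. It was also low in ask1, at 0.578 and 0.717 CPM in buds and open flowers against 12.2 and 12.4 in Col-0. In buds 38 genes rose and 32 fell, with EXO (AT4G08950) at 2.71 ± 0.29, DREB26 (AT1G21910) at 2.47 ± 0.22 and BGLU28 (AT2G44460) at -2.40 ± 0.24 among them. In open flowers 7 rose and 2 fell, with the sulfur-deficiency genes ATSDI1 (AT5G48850) at 2.59 ± 0.27 and LSU3 (AT3G49570) at 2.51 ± 0.30 among the rises. Both of those fell in ASK1 WT buds, where they stood at -2.30 ± 0.26 and -2.15 ± 0.26. MAF5 in buds lost its call without ASK1 WT bud replicate 1 (-2.88). EXO lost its call without ASK1 WT bud replicate 1 (2.35), Col-0 bud replicate 1 (2.45) or Col-0 bud replicate 2 (3.02), and DREB26 (2.46 and 2.43) and BGLU28 (-2.64 and -2.20) lost theirs without ASK1 WT bud replicate 1 or Col-0 bud replicate 2. In buds ATSDI1 and LSU3 lost theirs without ASK1 WT bud replicate 1 (-2.32 and -2.44), ASK1 WT bud replicate 2 (-2.28 and -1.89) or Col-0 bud replicate 2 (-2.14 and -1.80). In open flowers they lost theirs without ASK1 WT flower replicate 1 (2.53 and 2.37), ASK1 WT flower replicate 2 (2.64 and 2.63) or Col-0 flower replicate 1 (2.22 and 2.31), and LSU3 also without Col-0 flower replicate 2 (2.73). LSU genes are close paralogs and uncertain.

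Of 21 lists, 2 passed between the controls in buds and 6 in open flowers. In buds the test of the SCF partners pointed downward (limma camera adjusted p = 0.0336 and estimated-correlation adjusted p = 0.990) with 1 of 27 falling, and that of the clock genes upward (adjusted p = 0.0336 and estimated-correlation adjusted p = 0.990) with 1 of 17 rising. In open flowers the tests of jasmonate (adjusted p = 7.75e-05 and estimated-correlation adjusted p = 0.391), ethylene (adjusted p = 2.91e-04 and estimated-correlation adjusted p = 0.391), SCF (adjusted p = 0.0135 and estimated-correlation adjusted p = 0.704) and pollen (adjusted p = 0.0208 and estimated-correlation adjusted p = 0.963) pointed downward and those of salicylate (adjusted p = 1.51e-04 and estimated-correlation adjusted p = 0.391) and flavonoids (adjusted p = 0.0163 and estimated-correlation adjusted p = 0.584) upward. No member of these 6 lists passed the edgeR test on its own, 1 jasmonate gene passed DESeq2, and their medians lay between -0.21 and 0.29. The counts of 70 and 9 changed genes rested on each library. In buds they were 2 without ASK1 WT bud replicate 1, 27 without ASK1 WT bud replicate 2, 9 without Col-0 bud replicate 1 and 5 without Col-0 bud replicate 2. In open flowers they were 1 without ASK1 WT flower replicate 1, 1 without ASK1 WT flower replicate 2, 1 without Col-0 flower replicate 1 and 3 without Col-0 flower replicate 2.

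The change from buds to open flowers within each genotype asked whether flower maturation itself was altered. In Col-0, tapetum genes all but disappeared in open flowers. Counts of the glycine-rich protein genes GRP19 (AT5G07550) and GRP16 (AT5G07540) fell at least 15456-fold and at least 5281-fold, those of the lipid-transfer gene LTP12 (AT3G51590) fell at least 3741-fold, those of EXL6 fell at least 3223-fold and those of ATA27 (AT1G75940) fell 38606-fold with a 95% interval of 6929 to 1524900. SAG12 rose at least 8749-fold, sks8 rose at least 122-fold, EXPA25 rose at least 67.0-fold and GSTU3 (AT2G29470) rose at least 80.8-fold. Of 38 tapetum and pollen-wall genes, 36 fell and 2 did neither (36 falling when adjusted over the list alone), with a median of -9.81 (-8.81 with genes at 0 counts in a group set to their bound) and limma camera adjusted p = 1.92e-31 and estimated-correlation adjusted p = 1.76e-04. Of 12 senescence genes, 10 rose and 2 did neither (11 rising when adjusted over the list alone), with adjusted p = 7.03e-08 and estimated-correlation adjusted p = 0.0344. Of 276 F-box genes, 21 rose, 102 fell and 153 did neither (22 rising and 106 falling when adjusted over the list alone), with adjusted p = 8.40e-07 and estimated-correlation adjusted p = 0.0344. The tests of these 3 lists pointed the same way in ASK1 WT (tapetum adjusted p = 1.55e-33 and estimated-correlation adjusted p = 1.45e-04, senescence adjusted p = 4.23e-09 and estimated-correlation adjusted p = 0.0313, F-box adjusted p = 4.62e-06 and estimated-correlation adjusted p = 0.0313) and in ask1 (tapetum adjusted p = 5.90e-34 and estimated-correlation adjusted p = 1.40e-04, senescence adjusted p = 7.37e-06 and estimated-correlation adjusted p = 0.113, F-box adjusted p = 0.00574 and estimated-correlation adjusted p = 0.189). The size of the change in ask1 differed from that in ASK1 WT for senescence (adjusted p = 0.00143 and estimated-correlation adjusted p = 0.194) and F-box genes (adjusted p = 0.00788 and estimated-correlation adjusted p = 0.194). Jasmonate genes turned round, with 22 of 42 rising and 5 falling in Col-0 (adjusted p = 0.00281 and estimated-correlation adjusted p = 0.3002), 15 and 4 in ASK1 WT (adjusted p = 0.0192 and estimated-correlation adjusted p = 0.426) and 10 and 21 in ask1 (adjusted p = 0.0194 and estimated-correlation adjusted p = 0.450). Of 25 cell-cycle genes, 4 fell in Col-0 (adjusted p = 0.0900 and estimated-correlation adjusted p = 0.577), 5 in ASK1 WT (adjusted p = 0.221 and estimated-correlation adjusted p = 0.736) and 19 in ask1 (adjusted p = 5.97e-08 and estimated-correlation adjusted p = 0.189). Of 27 photosynthesis genes, 0, 2 and 11 rose, with adjusted p = 0.00774 and estimated-correlation adjusted p = 0.655 in ask1. In all, 4105 genes rose and 3737 fell in Col-0, 4032 and 3706 in ASK1 WT, and 4857 and 3391 in ask1. ASK1 WT shared 81.8% of the Col-0 rises and 80.7% of the falls, and ask1 shared 70.2% and 56.6%. Without ask1 flower replicate 2 the ask1 total was 12818. GRP16 overlaps an opposite-strand gene and is uncertain.

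A test of the difference asked which ask1 effects depended on the tissue. The trypsin inhibitor gene TI1 rose in buds, and its effect in open flowers less that in buds was -7.47 ± 0.59 (edgeR Benjamini-Hochberg adjusted p = 4.61e-04). HA9 (AT1G80660), a proton pump gene, had a higher effect in open flowers than in buds (5.81 ± 0.78) and the glucanase gene PR2 a lower one (-7.02 ± 1.11). In all, 975 genes had a higher effect and 517 a lower one in open flowers. The total of 1492 was 872 without ask1 bud replicate 1, 3213 without ask1 flower replicate 1, 8565 without ask1 flower replicate 2, 510 without ASK1 WT bud replicate 1, 601 without ASK1 WT bud replicate 2, 497 without ASK1 WT flower replicate 1 and 480 without ASK1 WT flower replicate 2. The balance was not stable. It was 1115 higher and 2098 lower without ask1 flower replicate 1, 1615 and 2510 without that library and ask1 bud replicate 2, and 714 and 748 without the low-count filter. HA9 overlaps an opposite-strand gene and is uncertain.

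Genes near ASK1 were counted to ask whether changed genes gathered around the insertion. Of 487 tested genes within 1 Mb of ASK1, 132 changed in buds and 163 in open flowers against ASK1 WT. The odds ratios by Fisher's exact test (two-sided) were 1.07 and 1.18 against ASK1 WT, and 0.926 and 1.26 against Col-0. Only the last had an unadjusted p of 0.0233, which became 0.140 after adjustment over the 6 comparisons. The outcome depended on the window. At 2 Mb the odds ratios were 1.197 in buds and 1.23 in open flowers against ASK1 WT (adjusted p = 0.0269 and 0.00996) and 1.304 in open flowers against Col-0 (adjusted p = 0.00117).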

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

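The tests of gene length as the whole cause and of low counts had their outcomes written down beforehand, and the other tests of causes given here were chosen only after the result was seen. The genes and lists of the next 2 paragraphs were set apart because the ask1 effect, or the difference between the controls, was not the same in buds and open flowers by a test of the difference itself. The 3 patterns after them were added once they had been noticed in the results.

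The ask1 effect differed between tissues for 1492 genes (edgeR quasi-likelihood, Benjamini-Hochberg). Effects were higher in open flowers than in buds for NIP4;1 (AT5G37810) (9.02 ± 1.76), CCOAMT (7.82 ± 1.43), LCR5 (AT2G28355) (7.37 ± 1.403), CYP71B8 (AT5G35715) (6.40 ± 1.19) and HA9 (5.81 ± 0.78, adjusted p = 0.00281). They were lower for RRTF1 (-11.15 ± 1.98), DDF1 (-8.61 ± 2.17), TI1 (-7.47 ± 0.59, adjusted p = 4.61e-04), MYB15 (AT3G23250) (-7.15 ± 1.69) and PR2 (-7.02 ± 1.11, adjusted p = 0.00634). HA9, TI1 and PR2 kept their calls whichever library was left out. NIP4;1 lost its call without ask1 flower replicate 2 (7.57), ASK1 WT flower replicate 1 (8.98) or ASK1 WT flower replicate 2 (8.93). CCOAMT lost it without ASK1 WT bud replicate 2 (7.23) or ASK1 WT flower replicate 2 (7.29), and LCR5 without ask1 flower replicate 1 (5.99) or ASK1 WT flower replicate 2 (6.43). CYP71B8 lost it without ask1 bud replicate 1 (6.40), ASK1 WT bud replicate 2 (6.26) or ASK1 WT flower replicate 2 (6.24). RRTF1 lost it without ask1 flower replicate 1 (-11.43), ask1 flower replicate 2 (-10.92), ASK1 WT bud replicate 1 (-10.91) or ASK1 WT bud replicate 2 (-11.52). MYB15 lost it without ask1 bud replicate 2 (-6.06), ASK1 WT bud replicate 1 (-7.17), ASK1 WT bud replicate 2 (-7.14), ASK1 WT flower replicate 1 (-7.45) or ASK1 WT flower replicate 2 (-6.87). DDF1 lost it without ask1 bud replicate 1 (-8.89), ask1 bud replicate 2 (-8.33), ask1 flower replicate 1 (-9.07), ask1 flower replicate 2 (-8.29), ASK1 WT bud replicate 1 (-7.90), ASK1 WT bud replicate 2 (-10.92) or ASK1 WT flower replicate 2 (-7.52). LCR5 was at 11.54 without ASK1 WT flower replicate 1.

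Among the gene lists, the median difference of the ask1 effect (open flowers less buds, log2) was 1.47 for pollen (1.43 without genes at 0 counts in a group), with 8 members higher and 1 lower (16 and 2 adjusted over the list alone) and limma camera adjusted p = 0.00212 and estimated-correlation adjusted p = 0.718. It was -0.95 for jasmonate (-0.90 without such genes, 6 higher and 17 lower, 8 and 25 adjusted over the list alone, adjusted p = 5.15e-07 and estimated-correlation adjusted p = 0.194) and -0.68 for the cell cycle (7 lower, 15 adjusted over the list alone, adjusted p = 6.45e-09 and estimated-correlation adjusted p = 0.194). It was 0.72 for the clock (4 higher, 7 adjusted over the list alone, adjusted p = 0.00315 and estimated-correlation adjusted p = 0.421) and -0.90 for senescence (-0.66 without such genes, 3 lower, 1 higher and 6 lower adjusted over the list alone, adjusted p = 0.00143 and estimated-correlation adjusted p = 0.194). Salicylate and defence stood at -0.69 (-0.66 without such genes, 1 higher and 5 lower, 1 and 8 adjusted over the list alone, adjusted p = 0.00315 and estimated-correlation adjusted p = 0.421) and ethylene at -0.19 (-0.17 without such genes, 2 lower, 3 adjusted over the list alone, adjusted p = 0.0220 and estimated-correlation adjusted p = 0.439). F-box genes stood at 0.29 (0.31 without such genes, 6 higher and 1 lower, none adjusted over the list alone, adjusted p = 0.00788 and estimated-correlation adjusted p = 0.194). Flavonoids stood at -0.34 with no single member past the edgeR test (adjusted p = 0.0431 and estimated-correlation adjusted p = 0.518). None passed with the estimated correlation. Ethylene did not pass with the length trend removed (adjusted p = 0.107) or without ask1 flower replicate 1 (adjusted p = 0.236), salicylate and defence did not pass without that library (adjusted p = 0.0814), and F-box genes did not with the length trend removed (adjusted p = 0.0602). The difference between ASK1 WT and Col-0 differed between tissues for 17 genes, 14 higher and 3 lower in open flowers.

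The ask1 open-flower libraries lay furthest apart of all pairs. Replicate 1 had a rank correlation of -0.467 with exon length against -0.0724 to 0.0753 in the other libraries, which is consistent with a length-dependent bias in that library. Length was not the whole cause, since 1492 genes still lay over 2-fold apart with the trend removed, against 424 to 565 in the control pairs. What remained was close to the ask1 bud pair, with 1290 genes and r = 0.984 against r = 0.982 in open flowers after removal. Depth was excluded, since the library totals differed by a ratio of 1.02. No biological explanation was tested, because the labels gave no difference between the replicates.

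Of 17 clock genes, 13 moved in the same direction in both ask1 tissues, 7 rising and 6 falling. Length bias was excluded, since 13 of the 13 shared genes kept their calls with the length trend removed, and a single library was excluded, since 10 kept them whichever library was left out. Collection of ask1 tissue at a later hour could not be separated from an effect of the genotype. The same limit holds for any changed gene outside this list whose level follows the hour of day. The labels gave the same hour for all samples but did not say that they were collected together. The ask1 effect differed between tissues for 4 clock genes, and BOA moved in opposite directions, which counts against 1 shared shift in hour only if both tissues were taken at the same time.

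By the fitted log2 fold change, 13 genes were at least 16-fold lower in ask1 in both tissues against both controls. Several held 0 counts in ask1, and the lowest bound from counts ran from 1.83-fold to 48.9-fold and reached 16-fold for only 1 gene. Of these, 4 lay within 2 Mb of ASK1 (30.8% against 4.44% of tested genes, one-sided Fisher's exact test, p = 0.00201), in line with sequence linked to ASK1 that differs from the controls. That could not account for all of them, since 9 lay elsewhere. Low counts were excluded as the cause of a fall for the 11 genes with a lower bound of at least 4-fold in all 4 comparisons, but the size of the fall was not fixed, and the other 2 genes stayed open. The biological alternative, a direct effect of ASK1 loss, was not separable by the genotypes sampled.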

How the results depend on the processing

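The tests with the length trend removed and with both uneven ask1 libraries left out were chosen only after the result was seen. No paired analysis was possible because replicate numbers reflect only the order of deposition. Where no cause is given, the cause was not tested.

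Under the alternatives other than leaving out 1 library, 87 counts of changed genes or passing lists stayed within 1.5 times their value and 29 moved further. Of the results for named genes, 1367 kept their side of the threshold, 79 lost their call, 2 gained one and 0 changed direction. Among single lists, 292 kept their side, 34 lost it and 10 gained it. When 1 library of a comparison was left out, 40 counts stayed within 1.5 times their value and 40 moved further, and 957 results for named genes were the same, 243 lost their call and 8 gained one. Single lists were the same in 308 cases, lost in 15, gained in 12 and reversed in 1, the 26S proteasome in open flowers without ask1 flower replicate 1 (adjusted p = 0.382 and downward, in a range from 1.84e-06 to 0.382).

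An added 2-fold minimum, a stricter threshold by construction, gave 2997 and 2871 genes for ask1 against ASK1 WT in buds and open flowers, 2420 and 2517 against Col-0, and 2175 and 2175 against both controls. It gave 1318 shared between tissues and 4995, 4800 and 4606 between tissues in Col-0, ASK1 WT and ask1. Fitting only the libraries compared gave 7565 and 6299 genes in buds against ASK1 WT and Col-0. It gave 2109 and 1653 genes in open flowers against ASK1 WT and Col-0, 1485 against both, 1352 shared between tissues, 513 for the tissue difference of the ask1 effect and 3468 between tissues in ask1. For ASK1 WT against Col-0 it gave 748 in buds and 397 in open flowers, and DESeq2 gave 298 and 31. ASK1 itself had an adjusted p of 0.0649 in buds against ASK1 WT in that smaller fit. With the length trend removed, ASK1 WT against Col-0 gave 178 genes in buds and the tissue difference of the ask1 effect gave 2390. Without both uneven ask1 libraries, buds against Col-0 gave 7425, buds against both controls 6206 and the tissue difference 4125. The cause was not tested for the changes under DESeq2, the smaller fit, length removal and the removal of both libraries.

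With the correlation between list members estimated, 0 lists passed in buds against ASK1 WT (from 5), 0 in open flowers against ASK1 WT (from 8), 0 in buds against Col-0 (from 6) and 0 in open flowers against Col-0 (from 8). Around ASK1, a 2 Mb window gave odds ratios of 1.197 in buds and 1.23 in open flowers against ASK1 WT and 1.304 in open flowers against Col-0, all past the threshold. Open flowers against Col-0 also passed with RLE factors (1.31) and without the low-count filter (1.39), as did open flowers against ASK1 WT without the filter (1.39). The cause was not tested.

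Leaving out each library of a comparison in turn gave from 3399 to 3839 genes in buds and from 3159 to 11550 in open flowers against ASK1 WT, and from 2559 to 3129 and from 2882 to 11247 against Col-0. Against both controls the range was 2453 to 2854 in buds and 2773 to 10195 in open flowers, and 1772 to 4348 for genes shared between tissues. ASK1 WT against Col-0 gave 2 to 27 genes in buds and 1 to 3 in open flowers, and the tissue difference of the ask1 effect 480 to 8565. Between tissues the range was 5551 to 6110 in Col-0, 5538 to 5624 in ASK1 WT and 5575 to 12818 in ask1. Passing lists numbered 5 to 8 in buds and 5 to 8 in open flowers against ASK1 WT, and 5 to 6 and 6 to 8 against Col-0. Without ask1 flower replicate 1, which lies outside the bud comparisons but shares their spread, 8 lists passed in buds against ASK1 WT and 7 against Col-0. Odds ratios near ASK1 ranged from 0.850 to 0.993 in buds and 1.07 to 1.17 in open flowers against ASK1 WT, from 0.775 to 0.958 and 1.09 to 1.19 against Col-0, and were 0 between the controls, against 0.636 in buds and 0 in open flowers with all libraries. The cause of the changes in counts was not tested. A lone library was assumed to vary like the other groups.

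Depth limited weakly expressed genes. A count of 0 allowed up to 0.128 to 0.218 CPM depending on the library.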

Other observations

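The tests of the gene lists given here were chosen only after the result was seen, from single genes noticed among the changed ones. The lists hold the genes that prompted them, so their tests were not independent of that choice. Of 16 cold-regulated genes, 10 rose and 1 fell in ask1 buds (limma camera adjusted p = 9.62e-07, estimated-correlation adjusted p = 0.0797). LTI78 (AT5G52310) was at 3.21 ± 0.26, COR15B (AT2G42530) at 2.38 ± 0.18 and LTI30 (AT3G50970) at 3.80 ± 0.55. In open flowers 8 rose (adjusted p = 7.71e-06, estimated-correlation adjusted p = 0.0900). Against Col-0, 10 rose in buds (adjusted p = 7.49e-08, estimated-correlation adjusted p = 0.0279) and 8 in open flowers (adjusted p = 3.60e-05, estimated-correlation adjusted p = 0.127). Some were uneven, with CBF1 (AT4G25490), CBF2 (AT4G25470) and ZAT10 (AT1G27730) at 0.491, 0.491 and 3.22 CPM in ask1 bud replicate 1 and at 4.47, 4.74 and 21.5 CPM in replicate 2. Of 12 iron-deficiency genes, 4 rose in buds (adjusted p = 0.00740, estimated-correlation adjusted p = 0.288) and 8 in open flowers (adjusted p = 3.76e-05, estimated-correlation adjusted p = 0.123), with the peptide genes IMA1 (AT1G47400) at 4.80 ± 0.78 and IMA2 (AT1G47395) at 4.93 ± 0.68. Against Col-0, 3 rose in buds (adjusted p = 0.0122, estimated-correlation adjusted p = 0.317) and 7 in open flowers (adjusted p = 1.49e-04, estimated-correlation adjusted p = 0.212). In buds the rise of IMA1, IMA2 and IMA3 (AT2G30766), 3 of the 4 genes past the test against ASK1 WT, lay in 1 library. They stood at 6.11, 4.58 and 14.8 CPM in ask1 bud replicate 1 and at 0.610, 1.08 and 1.02 CPM in replicate 2, with the control buds at 0.393 to 1.34 CPM. COR15B and IMA3 overlap genes on the opposite strand and IMA1 and IMA2, like CBF1 and CBF2, are close paralogs, so all 6 are uncertain. Fits without single libraries were not run for these members.

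Sulfur-deficiency genes fell in ask1 in 3 of 4 comparisons, and several of them also differed between the controls. Of 15 tested, 13 fell in ask1 buds (adjusted p = 1.65e-07, estimated-correlation adjusted p = 0.0951) and 11 in ask1 open flowers (adjusted p = 9.68e-08, estimated-correlation adjusted p = 0.0900) against ASK1 WT, including SULTR1;2 (AT1G78000) at -2.34 ± 0.21 and SDI2 (AT1G04770) at -1.75 ± 0.19 in buds. Against Col-0, 15 fell in buds (adjusted p = 1.20e-14, estimated-correlation adjusted p = 0.0279), whereas in open flowers 1 rose and 4 fell, with a median of -0.43 (adjusted p = 0.0735, estimated-correlation adjusted p = 0.482). Between the controls, 7 were lower in ASK1 WT buds and 7 were higher in ASK1 WT open flowers by the edgeR test of each gene. Members such as ATSDI1, LSU3 and BGLU28 had been seen to differ between the controls before the list was chosen, so the list tests between the controls were run but not relied on. SDI2 overlaps a gene on the opposite strand and is uncertain.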
